A study of Homo sapiens with 5 samples.

How the data were processed

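RNA was sequenced from 5 bulk libraries in 2 groups. KC is human epidermal keratinocytes cultured from skin at passage 2 in a serum-free keratinocyte medium (3 libraries, KC1 to KC3). KCNC is the neural crest cells induced from such keratinocytes (2 libraries, KCNC1 and KCNC2), which, per the labels, spent 10 days on collagen I in an endothelial basal medium with 2% serum, heparin, ascorbic acid, hydrocortisone, 10 ng/ml FGF2 and 10 ng/ml IGF1. The labels speak of 3 donors. Further libraries are not analysed here.

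The deposited files hold raw counts per gene symbol, 1 library per file and not normalized. Per the submitters' processing notes, TopHat2 2.0.11, DESeq2 and the human build hg19 were used. The counting tool, the annotation and the strand setting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene could not be told apart. Genes with near-identical copies, such as HSPA1A and HSPA1B or the KLRC family, are uncertain for the same reason. The reference at hand was of another build, so no coordinates are given. It served only for gene names, with 17495 symbols found in its name table, and to leave 35 sex-informative genes out of every test and output, which left 18941 genes.

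Total counts, in M (1e6 counts), were 24.7 in KC1, 52.0 in KC2, 44.0 in KC3, 17.9 in KCNC1 and 40.4 in KCNC2. A count of 0 in a library allows up to 3 counts, which is between 0.0577 and 0.167 CPM (counts per 1e6 counts). Over the KC group of 120.6 M counts the same limit is 0.0249 CPM. Such limits and all count intervals (95%, exact) cover counting error only, because reads without molecular identifiers are not independent molecules. No libraries were duplicates, since the chi-square of counts per degree of freedom between libraries of a group was 22.6 at the lowest (KC1 against KC3) and 380 at the highest (KCNC1 against KCNC2).

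Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10), libraries were scaled by TMM, dispersions were estimated with estimateDisp, and the quasi-likelihood F test was run with a robust fit on a design with group as the only term. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2 scale as KCNC over KC, and the standard error (SE) is the absolute log2 fold change divided by the square root of F. Levels are TMM-normalized CPM unless said to be of library totals. A fold against a group with no counts is a lower bound against 3 counts over that group, and folds of genes with 1 to 3 counts in a group are pooled ratios with an exact interval, both on library totals.

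Before the data were examined, 28 gene lists with 458 members were fixed for keratinocyte, mesenchymal and neural crest identity, other cell types and pathways, and 457 members were found. Lists with at least 3 tested members (27) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists. The rule for named genes was also fixed then. It took the 6 largest increases and 6 largest decreases among changed genes with at least 10 CPM in the higher group and no overlap between groups, 17 identity genes whatever their result, and up to 2 members of each list with the smallest adjusted p (all members that passed where these were 5 or fewer, and the 2 with the highest mean CPM where none passed). Genes named outside it are said to be so.

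The procedure was tested on simulated counts for KCNC against KC, with 13876 genes of which 200 were changed. It recovered 0% of genes changed 2-fold, 44% at 4-fold, 82% at 8-fold and 96% at 16-fold, and no call had the wrong sign. False calls were 12, or 9.76% of all calls, which is above the nominal 5% that the threshold sets. A simulated list raised 4-fold gave a camera p of 1.32e-21, and 1 of 50 random lists had a p under 0.05. Simulated genes varied independently, with the same dispersion in both groups. Estimated correlations in the real lists reached 0.99 (epithelial junction genes), so the simulation does not show how the list test behaves here. Nor does it cover the wider spread between the KCNC libraries, for lists or for genes. The share of changed genes was also far smaller than in the data, where 2630 of 14056 tested genes passed. With fewer changed genes the adjusted threshold is harder to reach, so the recovered percents do not carry over to the data.

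Whether replicate numbers pair the libraries was checked. The labels describe RNA from KC and from the KCNC derived from them, by donor, without stating that a number marks a donor. The difference KC1 minus KC2 correlated across genes with KCNC1 minus KCNC2 at −0.242, where genes are not independent replicates. The fit without the replicate number as a block was fixed as the main one, and the blocked result is printed beside the counts.

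Alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, 3 other scalings, 2 other filters, the replicate block, each library left out in turn, counts thinned to the smallest library, a fit that is not robust, stricter thresholds, and for lists an estimated correlation and fry. Fry asks whether a list changed at all and camera whether it changed more than other genes, so they answer different questions. The crossed numbers and the blocked fits with DESeq2 and limma-voom were chosen after seeing the data. With 3 against 2 libraries, other splits of the samples and the search for outlying libraries were not run, since these need larger groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining values and the plots.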

Results

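The series compared cultured human epidermal keratinocytes (KC, 3 libraries) with neural crest cells induced from keratinocytes over 10 days in medium with FGF2 and IGF1 (KCNC, 2 libraries). The neural crest is the embryonic population that gives rise to pigment cells, peripheral neurons and glia, and parts of the facial skeleton. The comparison addressed how far the transcriptome of the induced cells moved from keratinocytes toward neural crest. The labels name total RNA, and values are read counts per gene. Total counts ranged from 24.7 to 52.0 M in KC and from 17.9 to 40.4 M in KCNC. The labels name 3 donors, and p-values measure only the spread between these 5 libraries.

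KRT5 and KRT14, the main basal keratins, were lower in KCNC, and some mesenchymal and neural crest genes were higher. KRT5, a basal keratin, stood at 29682 ± 2161 CPM in KC (SD, n = 3) and 468 ± 521 CPM in KCNC (SD, n = 2), a log2 fold change of −5.99 ± 1.11 (SE, edgeR adjusted p = 0.0269), or −5.14 without KCNC1 and −8.22 without KCNC2. VIM, the intermediate filament of mesenchymal cells, rose from 464 ± 78.9 to 5404 ± 1261 CPM (log2 fold change 3.54 ± 0.25, edgeR adjusted p = 0.00428). PAX3, a transcription factor of the neural plate border, rose from 0.404 ± 0.360 to 149 ± 9.61 CPM (8.65 ± 0.84, edgeR adjusted p = 0.00716). Of 14056 genes tested, 2630 changed, 1627 of them higher and 1003 lower in KCNC, and 2225 of them changed at least 2-fold. Groups did not overlap in 7856 genes, or 55.9%, where chance gives 20% if all 5 libraries are independent. KC3 may not be, as described below, and genes are not independent of each other, so the excess is no test.

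These counts depended on which libraries entered. Genes changed numbered 34 without KC3, 235 without KC1 and 266 without KC2. Without KC3, 2619 of the 2630 genes had the same sign of change, where genes no longer tested count against. Leaving out 1 of the libraries that gave a call can hardly turn its sign, so the signs are no separate support. Of 92 named genes tested, 83 passed. Of these 83, 73 no longer passed without KC3, 52 without KC1, 48 without KC2 and 8 with limma-voom. Members of the gene lists that were called numbered 148, against 9 without KC3, 39 without KC1, 40 without KC2, 300 without KCNC1 and 298 without KCNC2. Each gene of the naming rule that passed had both KCNC libraries above or both below all 3 KC libraries. In 30 of these 83 genes KCNC1 and KCNC2 stood over 2-fold apart. With the replicate number as a block, which leaves 1 residual degree of freedom, edgeR called 0 genes, with 1987 at an unadjusted p under 0.05, limma-voom called 0, with 2582 unadjusted, and DESeq2 called 1679, so no gene called here was called in the blocked edgeR fit, where all 2630 had the same sign. Adjusted p-values of genes are from edgeR's quasi-likelihood test, and those of gene lists from limma's camera. Of 27 lists tested, 15 passed with the preset correlation and 0 with a correlation estimated per list, where 2 had an unadjusted p under 0.05 (neural crest surface and migration genes, p = 0.0474, and glucocorticoid response genes, p = 0.0471), and fry called 17, among them 13 of the 15.

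The libraries of a group were not alike. The first principal component held 69.5% of the variance and parted KC from KCNC, and the second held 25.4% and parted KCNC1 from KCNC2. Across genes, log2 CPM correlated at 0.975 to 0.988 between KC libraries, at 0.844 between the KCNC libraries and at 0.752 to 0.795 between the groups (genes are not independent replicates). KC3 lay between KC1 and KC2 in most genes that stood far apart between them. Of 426 genes over 2-fold apart between KC1 and KC2 (mean over 100 counts, CPM of library totals), KC3 was between them in 97.2%, and 0 of 11206 genes had KC3 over 2-fold beyond both others, against 123 for KC2 and 53 for KC1.

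**Figure D1:**
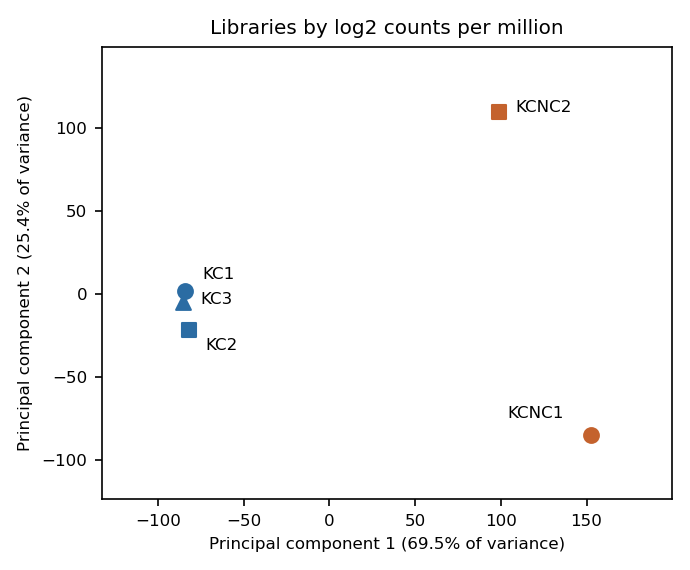
Libraries on the first 2 principal components of log2 CPM, 1 point per library, KC in blue and KCNC in orange. The 3 KC libraries lie together, and KCNC1 and KCNC2 lie apart from each other along the second component (25.4% of the variance).

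Among the largest decreases by rule were DSG1 and KRT1, which belong to a fixed keratinocyte list (values of genes in brackets are log2 fold changes ± SE, and CPM are means ± SD). FGFBP1, a carrier protein that binds fibroblast growth factors, fell from 1085 ± 74.4 to 4.57 ± 0.466 CPM (log2 fold change −7.89 ± 0.24, edgeR adjusted p = 0.0016). DSG1, a desmosomal cadherin of differentiating keratinocytes, had 2140 counts over the KC libraries and 2 over the KCNC libraries, a ratio 518-fold lower (95% interval 143 to 4278). KRT1, a suprabasal keratin, had 1177 against 2 counts, 285-fold lower (78.7 to 2354), and IGFL3 2464 against 3 counts, 397-fold lower (136 to 1929). KRT24 (−9.09 ± 1.44) and IFNK, an interferon of keratinocytes (−7.56 ± 0.71), completed the 6 largest decreases by rule.

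Among basal keratinocyte genes, 6 of 15 tested members fell and none rose, or 12 adjusted over the list alone. ITGA6, the hemidesmosomal integrin, fell from 1181 ± 109 to 70.4 ± 2.94 CPM (−4.07 ± 0.20, edgeR adjusted p = 0.00226), and DST (−3.23 ± 0.26), KRT14 (−5.59 ± 1.12) and TP63, a regulator of stratified epithelium (−4.99 ± 1.10), fell too. KRT14 stood at 60.8 CPM in KCNC1 and 552 CPM in KCNC2 (log2 fold change −4.73 without KCNC1 and −7.92 without KCNC2), and TP63 at 0.690 and 8.25 CPM (−4.12 and −7.70). KRT15, a basal keratin named after its value was seen, stood at 8.77 CPM in KCNC1 and 429 CPM in KCNC2, against 312 ± 79.0 CPM in KC, and did not pass (edgeR adjusted p = 0.820). The members summed to 70421 to 82955 CPM in KC, 1930 CPM in KCNC1 and 7848 CPM in KCNC2. The median log2 fold change was −3.58, and the list passed (camera adjusted p = 4.51e-06), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 2.42e-09 over 12 alternatives. Members called lower were 1 without KC3, 2 without KC1, 2 without KC2, 12 without KCNC1 and 14 without KCNC2.

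Suprabasal and cornified envelope genes had 6 of 25 tested members lower (6 adjusted over the list alone), with DSG1 and KRT1 leading. The members summed to 883 to 2147 CPM in KC, 34.8 CPM in KCNC1 and 1372 CPM in KCNC2, so the sum was lower in KCNC1 alone. Without KCNC2 22 members were called lower and none higher, and without KCNC1 7 were lower and 3 higher. With a median log2 fold change of −2.22 the list passed (camera adjusted p = 1.57e-05), with adjusted p = 0.550 with an estimated correlation, the upper end of a range from 3.91e-09 over 12 alternatives, and it did not pass without KCNC1 (adjusted p = 0.102). KRT10, another suprabasal keratin, stood at 15.7 ± 4.98 and 7.29 ± 1.88 CPM and did not pass (edgeR adjusted p = 0.0978). Stress and simple-epithelium keratins had 1 of 9 members lower, KRT18 (−2.61 ± 0.29, edgeR adjusted p = 0.0092), and 1 adjusted over the list alone. Over all genes DESeq2 called 7 of these keratins lower and limma-voom 6. Their sum was 31046 to 39104 CPM in KC2 and KC3, 40039 CPM in KC1, 428 CPM in KCNC1 and 5829 CPM in KCNC2, so more than KRT18 was lower. That list, with a median log2 fold change of −3.41, passed (camera adjusted p = 0.00124), with adjusted p = 0.550 with an estimated correlation, the upper end of a range from 1.38e-06, and it did not pass in fry (adjusted p = 0.0610).

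Epithelial junction and identity genes also passed as a list (median log2 fold change −2.67, camera adjusted p = 9.89e-05), with adjusted p = 0.574 with an estimated correlation, the upper end of a range from 1.53e-13, and they did not pass in fry (adjusted p = 0.145). PKP3, a desmosomal plaque protein, was the 1 of 21 members that fell (−3.72 ± 0.79, edgeR adjusted p = 0.0357), and 0 passed edgeR adjusted over the list alone (4 at an unadjusted p under 0.05, all lower). Over all genes DESeq2 called 9 members lower and limma-voom 5. CDH1, the epithelial cadherin, was at 459 ± 52.3 CPM in KC, 2.56 CPM in KCNC1 and 141 CPM in KCNC2 and did not pass (edgeR adjusted p = 0.262, 6.09e-07 to 0.474 over its alternatives). The members summed to 175 CPM in KCNC1 and 2511 CPM in KCNC2, against 6832 to 7585 CPM in KC. Without KCNC2 all 21 members were called lower, and without KCNC1 17 were lower and 2 higher.

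**Figure D2:**
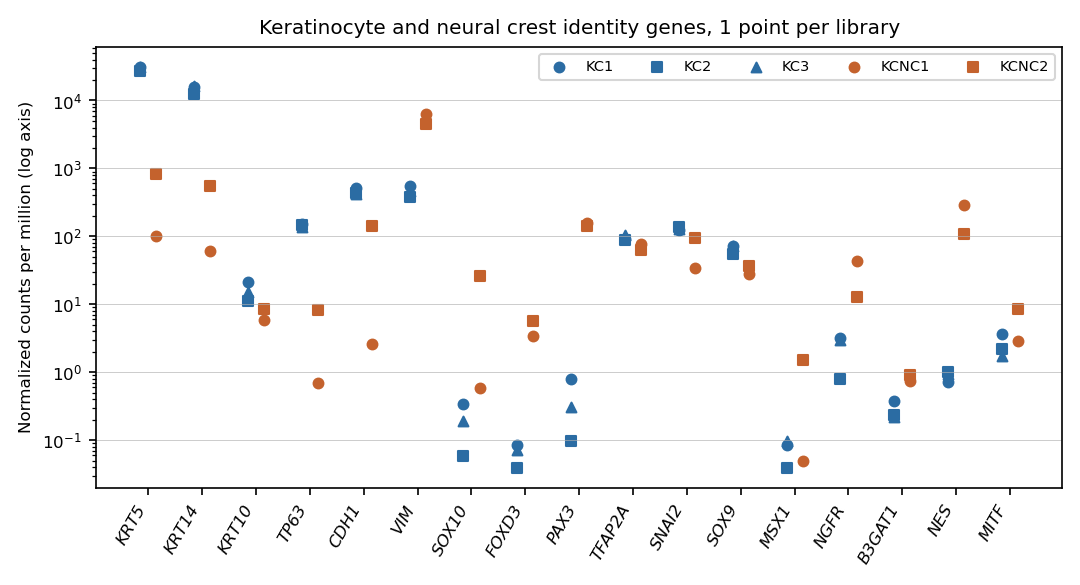
Normalized CPM (log axis) of 17 keratinocyte and neural crest identity genes, 1 point per library, KC in blue and KCNC in orange. KRT5 is far lower in both KCNC libraries, PAX3 and NES are far higher in both, and CDH1 and SOX10 differ widely between KCNC1 and KCNC2.

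Among mesenchymal and matrix genes, 13 of 20 members were higher and none lower (16 higher adjusted over the list alone). The median log2 fold change of the list was 3.24 and its camera adjusted p 1.33e-07, with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 2.52e-09. ZEB2, a repressor of epithelial genes, rose from 0.324 ± 0.0935 to 142 ± 44.9 CPM (8.77 ± 0.40, edgeR adjusted p = 0.00226), and FBN1, the microfibril protein fibrillin, from 7.53 ± 1.77 to 314 ± 34.1 CPM (5.38 ± 0.28, edgeR adjusted p = 0.00232). Members called higher were 2 without KC3, 8 without KC1, 8 without KC2, 18 without KCNC1 and 14 (with 1 lower) without KCNC2.

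Fibroblast genes had 8 of 12 tested members higher and 1 lower (10 and 2 adjusted over the list alone). COL1A1, a chain of type I collagen, rose from 21.5 ± 6.47 to 2719 ± 423 CPM (6.98 ± 0.35, edgeR adjusted p = 0.00226), and PDGFRB, a growth factor receptor of mesenchymal cells, from 0.349 ± 0.137 to 145 ± 16.2 CPM (8.70 ± 0.41, edgeR adjusted p = 0.00226). Other members, named after their values were seen, went differently. MFAP5 fell (−6.94 ± 0.58), and DCN, a proteoglycan of dermal fibroblasts, stood at 0.296 CPM in KCNC1 and 35.6 CPM in KCNC2 against 0.648 ± 0.158 in KC and did not pass (edgeR adjusted p = 0.105). Fibroblast genes passed as a list (median log2 fold change 7.41, camera adjusted p = 0.000614), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 0.000128.

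Neural crest specifier genes, the transcription factors that define the neural crest state, had 7 of 14 tested members higher and 2 lower (8 and 2 adjusted over the list alone). NR2F1 rose from 0.375 ± 0.122 to 188 ± 63.9 CPM (edgeR adjusted p = 0.00226), SNAI1 from 0.0996 ± 0.0175 to 10.3 ± 0.881 CPM (6.61 ± 0.39) and FOXD3 from 0.0652 ± 0.0231 to 4.52 ± 1.59 CPM (6.10 ± 0.59, edgeR adjusted p = 0.00674). SOX9 fell from 66.3 ± 10.6 CPM in KC (−1.05 ± 0.23, edgeR adjusted p = 0.0364), and MYC, named after its value was seen, fell too (−1.67 ± 0.19). SOX10, a regulator of neural crest and its glia and pigment cells, was at 0.591 CPM in KCNC1 and 26.3 CPM in KCNC2 against 0.196 ± 0.139 in KC and did not pass (edgeR adjusted p = 0.0613, 2.54e-05 to 0.582 over its alternatives). SNAI2 (130 ± 4.68 and 65.0 ± 42.8 CPM) did not pass either. As a list these genes passed (median log2 fold change 4.16, camera adjusted p = 0.00693), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 0.0021.

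Neural crest surface and migration genes had 8 of 14 tested members higher and 1 lower (10 and 2 adjusted over the list alone). NES, the intermediate filament of neural progenitors, rose from 0.886 ± 0.152 to 197 ± 125 CPM (7.78 ± 0.53, edgeR adjusted p = 0.00409), the integrin ITGA4 from 6.26 ± 0.561 to 114 ± 9.30 CPM (4.18 ± 0.17, edgeR adjusted p = 0.00226), and the neurotrophin receptor NGFR from 2.32 ± 1.32 to 28.2 ± 21.5 CPM (3.61 ± 0.81, edgeR adjusted p = 0.0401). EFNB2, named after its value was seen, fell (−1.40 ± 0.23). B3GAT1, an enzyme that makes the HNK1 epitope, stood at 0.277 ± 0.0890 and 0.832 ± 0.131 CPM and did not pass (edgeR adjusted p = 0.110). Their median log2 fold change was 2.16 and the list passed (camera adjusted p = 0.00545), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 0.00346, and it did not pass without KCNC2 (adjusted p = 0.0738).

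Neural plate border genes did not pass as a list (camera adjusted p = 0.900), except in fry (0.0288, in a range up to 0.977). PAX3 and GLI2 (5.38 ± 0.42, edgeR adjusted p = 0.00446) were the 2 of 9 tested members that rose (2 higher and 1 lower adjusted over the list alone). TFAP2A, a border gene that keratinocytes also express, stood at 95.1 ± 9.31 and 69.9 ± 10.5 CPM and did not pass (edgeR adjusted p = 0.143). MSX1 was not tested, with 8 counts over the KC libraries, 1 in KCNC1 and 60 in KCNC2.

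Genes of neural crest derivatives did not pass as lists in the unblocked fit, and some did in others. Melanocyte genes (camera adjusted p = 0.148, 0.0425 to 0.972 over the alternatives, the lowest with the replicate block) had 2 of 12 members higher and 1 lower (4 and 1 adjusted over the list alone). GPR143 rose (4.51 ± 0.48, edgeR adjusted p = 0.00841), RAB38 fell (−3.11 ± 0.25), and SLC45A2 had 174 counts in KCNC against 2 in KC, a 180-fold ratio (95% interval 49.0 to 1496), with 10 of the counts in KCNC1 and 164 in KCNC2 (0.493 and 4.10 CPM). DCT, a pigment enzyme named after its value was seen, had no counts in KCNC1 and stood at 5.80 CPM in KCNC2, against 0.166 ± 0.131 CPM in KC, and did not pass (edgeR adjusted p = 0.182). MITF, the regulator of pigment cells, was at 2.56 ± 1.03 and 5.73 ± 3.99 CPM and did not pass (edgeR adjusted p = 0.230). Schwann cell genes (camera adjusted p = 0.0894) passed with the block (adjusted p = 0.0330) and without KCNC1 (0.00762), in a range up to 0.583. They had L1CAM (2.04 ± 0.23), NCAM1 (6.46 ± 1.41) and S100B (6.34 ± 1.43) higher and POU3F1 lower, which had 91 counts in KC and 0 in KCNC (5 higher and 1 lower adjusted over the list alone). KCNC2 carried the values of NCAM1 (0.690 CPM in KCNC1, 16.4 CPM in KCNC2, log2 fold change 2.83 without KCNC2) and S100B (0.641 and 6.70 CPM).

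Neuron genes (camera adjusted p = 0.522) had STMN2 (9.89 ± 1.45) and TUBB3 (1.55 ± 0.34) higher and ISL1 lower (−4.12 ± 0.56), with 3 each way adjusted over the list alone. STMN2, a tubulin-binding protein of growing neurites, was at 8.63 CPM in KCNC1 and 129 CPM in KCNC2 (log2 fold change 6.89 without KCNC2).

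Markers of other cell types moved in part. Endothelial genes had 3 of 7 tested members higher (4 adjusted over the list alone), with ROBO4 (3.49 ± 0.36) and ESAM (6.14 ± 1.24) beside TIE1, which had 892 counts against 2, a 922-fold ratio (95% interval 254 to 7623). Endothelial genes passed as a list (median log2 fold change 3.49, camera adjusted p = 0.0145), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 0.00256, and did not pass without KC2 (adjusted p = 0.0991) or without KCNC2 (adjusted p = 0.0522). ESAM stood at 6.11 CPM in KCNC1 and 0.525 CPM in KCNC2, with a log2 fold change of 3.53 without KCNC1.

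Smooth muscle and contractile genes did not pass (camera adjusted p = 0.420), except in fry (0.0472, in a range up to 0.631). Of them, MYL9 (2.45 ± 0.26), TPM2 (1.23 ± 0.17) and CNN1 (4.02 ± 0.78) were higher, and SMTN (−1.61 ± 0.21) and TAGLN (−1.35 ± 0.25) lower, with 5 and 2 adjusted over the list alone. Of immune cell genes (camera adjusted p = 0.420), CD14 (5.71 ± 0.73) and HLA-DRA (8.56 ± 2.00) were higher (2 higher and 1 lower adjusted over the list alone). HLA-DRA stood at 0.641 CPM in KCNC1 and 26.5 CPM in KCNC2, and its log2 fold change was 4.14 without KCNC2. The Merkel cell list had 2 tested members and no list test, and PIEZO2, a mechanosensitive channel, rose (7.50 ± 0.48), with 2 higher adjusted over the list alone. Of pluripotency genes (camera adjusted p = 0.421), ZFP42 fell (−5.30 ± 0.66), the 1 of 5 members that passed, as it did adjusted over the list alone.

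HOX genes, which mark position along the body axis, passed as a list (median log2 fold change 0.77, also with genes without counts in KC at their bound, camera adjusted p = 0.0109), with adjusted p = 0.550 with an estimated correlation, the upper end of a range from 0.00516, and did not pass without KCNC2 (adjusted p = 0.262). Of 31 tested members 12 rose, 2 fell and 17 did not pass (13 higher and 2 lower adjusted over the list alone), so the HOX genes did not move as one. The 2 with the smallest adjusted p do not stand for the rest. HOXB2 rose from 0.183 ± 0.0484 to 31.4 ± 3.56 CPM (7.37 ± 0.33, edgeR adjusted p = 0.00226) and HOXB7 from 0.159 ± 0.0676 to 17.1 ± 1.57 CPM (6.66 ± 0.44, edgeR adjusted p = 0.00393).

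The largest increases came from a few genes nearly silent in KC. TLR4, an innate immune receptor, had 1031 counts over the KCNC libraries and 1 over the KC libraries, a 2131-fold ratio (95% interval 382 to 84237). RARB, a retinoic acid receptor, had 1003 against 1 count (2073-fold, 371 to 81951), MYOD1, a muscle transcription factor, 805 against 1 (1664-fold, 298 to 65790), and PTPRN 1813 against 2 (1873-fold, 518 to 15481). KLRC2, which shares reads with close family members and is uncertain, had 703 against 1 (1453-fold, 260 to 57464). These intervals cover counting error in the pooled counts and not the spread between KCNC libraries. PTPRN stood at 2.02 CPM in KCNC1 and 44.3 CPM in KCNC2, and its log2 fold change was 6.58 without KCNC2 and 11.09 without KCNC1. RARB stood at 5.08 and 22.5 CPM (8.69 without KCNC2, 10.91 without KCNC1) and MYOD1 had 645 and 160 counts (11.33 without KCNC2, 8.39 without KCNC1). STMN2 was the sixth by rule.

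Among cholesterol synthesis genes, 12 of 16 members were lower and none higher (15 lower adjusted over the list alone). MVD fell from 208 ± 15.9 to 37.2 ± 6.79 CPM (−2.49 ± 0.20, edgeR adjusted p = 0.00474) and DHCR7, which makes cholesterol in the last step of its pathway, from 282 ± 27.4 to 58.1 ± 22.9 CPM (−2.28 ± 0.31, edgeR adjusted p = 0.0132). Cholesterol synthesis genes passed as a list (median log2 fold change −2.24, camera adjusted p = 3.43e-07), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 5.93e-09. Members that edgeR called lower were 0 without KC3 (15 at an unadjusted p under 0.05), 1 without KC1, 1 without KC2, 16 without KCNC1 and 15 without KCNC2. Interferon response genes had 7 of 16 members lower (10 adjusted over the list alone). OAS3 fell from 158 ± 1.87 to 26.1 ± 1.20 CPM (−2.60 ± 0.15, edgeR adjusted p = 0.00315) and IFIT1 from 70.8 ± 1.01 to 12.6 ± 1.40 CPM (−2.50 ± 0.17, edgeR adjusted p = 0.00409). That list had a median log2 fold change of −2.07 and passed (camera adjusted p = 2.13e-05), but not with an estimated correlation (camera adjusted p = 0.460). Its mean log2 fold change was −1.81, or −1.32 without KCNC1 and −4.10 without KCNC2. Immediate-early and heat-shock genes had 3 of 11 members lower (6 adjusted over the list alone), FOS (−2.38 ± 0.40) and the near-identical pair HSPA1A (−1.15 ± 0.20) and HSPA1B (−1.17 ± 0.22), which share reads and are uncertain. They passed (median log2 fold change −0.83, camera adjusted p = 0.0141), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 0.00499, and did not pass without KCNC1 (adjusted p = 0.132).

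Lists tied to components of the induction medium were also tested (glucocorticoid, insulin-like growth factor, and FGF and ERK genes). No group isolated a component, so a response to any of them was not tested. Glucocorticoid response genes had 7 of 12 members higher and none lower (8 adjusted over the list alone), with CRISPLD2 rising from 1.93 ± 0.348 to 65.2 ± 13.8 CPM (5.08 ± 0.27, edgeR adjusted p = 0.00254) and KLF9 from 1.37 ± 0.469 to 38.8 ± 12.4 CPM (4.83 ± 0.43, edgeR adjusted p = 0.00577). Glucocorticoid response genes passed as a list (median log2 fold change 1.61, camera adjusted p = 0.000156), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 7.58e-05. Insulin-like growth factor axis genes had 7 of 12 members higher (8 adjusted over the list alone), with IGF2 rising from 0.150 ± 0.0529 to 40.4 ± 9.79 CPM (8.11 ± 0.38, edgeR adjusted p = 0.00226) and IGFBP4, a binding protein, from 33.6 ± 11.4 to 520 ± 19.0 CPM (3.95 ± 0.34). They passed (median log2 fold change 1.94, camera adjusted p = 0.00256), with adjusted p = 0.460 with an estimated correlation, the upper end of a range from 0.000338, and did not pass without KCNC2 (adjusted p = 0.146). FGF and ERK feedback genes did not pass as a list (camera adjusted p = 0.680). FGFR1 (4.29 ± 0.43), ETV1 (3.51 ± 0.63), SPRY1 (3.23 ± 0.49) and SPRY2 (1.46 ± 0.33) rose and DUSP6 fell (−1.63 ± 0.32), with 5 and 1 adjusted over the list alone.

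Other signalling lists did not pass in camera without the block. WNT target and antagonist genes (camera adjusted p = 0.562) passed in fry (0.0472, in a range up to 0.972). They had 5 of 17 members higher and 1 lower (6 and 1 adjusted over the list alone), led by AXIN2, a feedback target of the pathway (5.58 ± 0.49, edgeR adjusted p = 0.00575), and FZD7 (2.43 ± 0.24), with DKK1, named after its value was seen, lower (−1.78 ± 0.38). BMP and TGF-beta response genes (camera adjusted p = 0.0840) passed with the replicate block (0.0451) and in fry (0.0407), in a range up to 0.460. They had GREM1 (8.71 ± 0.73), SMAD6 (6.46 ± 1.05) and TGFB2 (3.20 ± 0.67) higher and NOG lower (−4.97 ± 0.49), with 3 and 1 adjusted over the list alone. Notch pathway genes (camera adjusted p = 0.694) had the ligands JAG1 (−1.51 ± 0.26), JAG2 (−3.42 ± 0.67) and DLL1 (−3.50 ± 0.59) and the receptor NOTCH1 (−2.13 ± 0.46) lower. HEYL had 94 counts in KCNC against 2 in KC (97.1-fold, 95% interval 26.2 to 814), and 3 higher and 4 lower passed adjusted over the list alone.

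**Figure D3:**
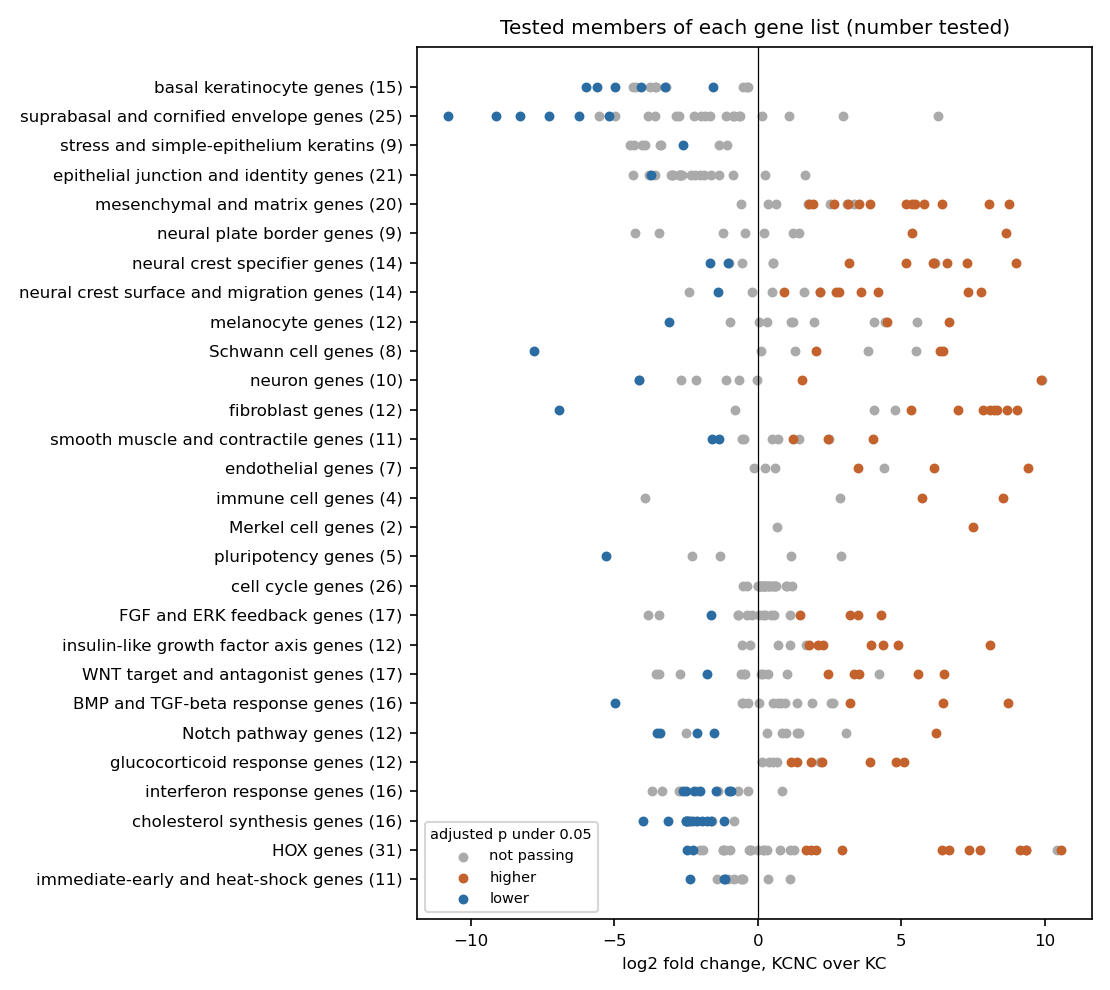
Log2 fold change (KCNC over KC) of each tested member of the 28 gene lists, 1 point per gene, orange where higher, blue where lower and grey where the edgeR test did not pass. Points of mesenchymal and fibroblast genes lie mostly to the right, those of cholesterol synthesis genes to the left, and all 26 cell cycle genes are grey.

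Cell cycle genes split the KCNC libraries. They summed to 2218 to 3429 CPM in KC, 6190 CPM in KCNC1 and 895 CPM in KCNC2. None of 26 members passed in the edgeR test, nor adjusted over the list alone, with 0 at an unadjusted p under 0.05 (DESeq2 and limma-voom also called 0), and the list did not pass (camera adjusted p = 0.561, 1.10e-07 to 0.904 over its alternatives). Without KCNC2, 23 members were called higher and the list passed upward, and without KCNC1, 24 were called lower and it passed downward (adjusted p = 1.10e-07). TOP2A, a topoisomerase of dividing cells, was at 196 ± 58.8 CPM in KC, 811 CPM in KCNC1 and 77.0 CPM in KCNC2, and MCM7, a replication helicase subunit, at 257 ± 39.2, 491 and 115 CPM. The camera direction was down for this list, with a median log2 fold change of 0.25 and a mean of 0.33. It was also down for neural plate border genes (median 0.21, mean 0.84), neuron genes (−0.89 and 0.65) and Notch pathway genes (0.58 and 0.10).

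**Figure D4:**
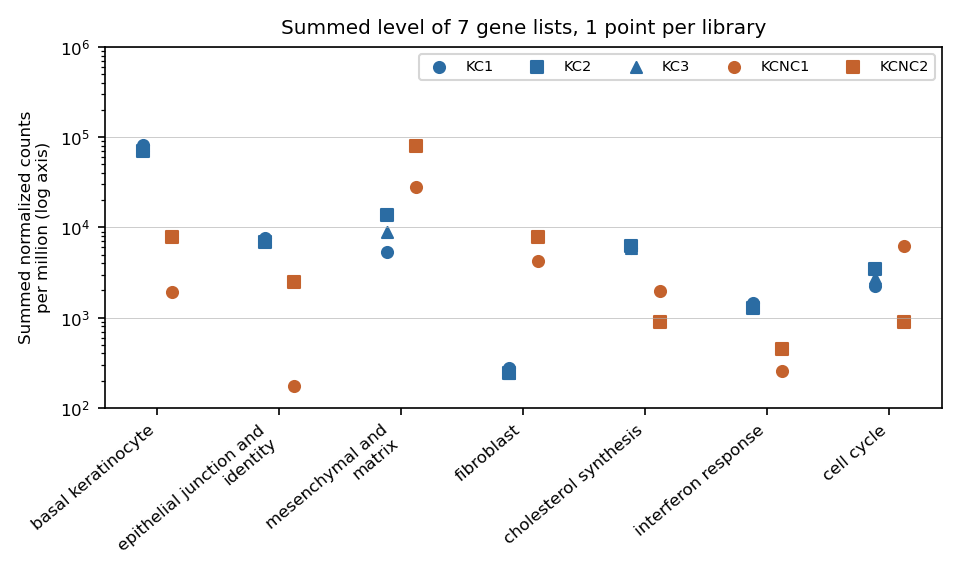
Summed normalized CPM (log axis) of 7 gene lists, 1 point per library, KC in blue and KCNC in orange. Cell cycle genes lie above the KC libraries in KCNC1 (6190 CPM) and below them in KCNC2 (895 CPM), and epithelial junction genes are at 175 CPM in KCNC1 and 2511 CPM in KCNC2.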

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

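The crossed replicate numbers and the blocked fits with DESeq2 and with limma-voom were tests chosen after seeing the data, and the other alternatives were fixed earlier. Under other scalings (RLE, upper quartile), the fit that is not robust, thinning and both filters, the number of genes changed was within 1.5 times that of 2630. Library totals moved the median of all genes by 0.14 on the log2 scale and gave 2739 genes, 71.7% of them higher, against 61.9%. With DESeq2 4922 genes changed (2745 higher, 2177 lower), which included all 2630, and limma-voom called 2486 of the 2630. MYOD1, PTPRN, STMN2, KRT24, NCAM1, S100B, ESAM and HLA-DRA did not pass in limma-voom (adjusted p from 0.0574 for MYOD1 to 0.169 for KRT24), where 1 Schwann cell gene was higher, against 3, and 6 fibroblast genes, against 8. An adjusted p under 0.01 left 442 genes (328 higher, 114 lower).

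With the replicate block edgeR called 0 genes changed, 0 higher and 0 lower, both with all 5 libraries (1987 genes at an unadjusted p under 0.05) and with pairs only (1985). Crossed replicate numbers also gave 0 changed, 0 higher and 0 lower (3038 at an unadjusted p under 0.05). The blocked limma-voom fit gave 0, 0 and 0 (2582 unadjusted), and the blocked DESeq2 fit 1679 genes (948 higher, 731 lower). These fits leave 1 residual degree of freedom against 3 without the block, and the smallest edgeR adjusted p was 0.194 with the block.

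Leaving out 1 library in turn, genes changed ranged from 34 (without KC3) to 7310 (without KCNC1), genes higher from 30 to 3816 and genes lower from 4 to 3494. Without a KCNC library the lone sample is assumed to vary like the KC group, which is the more uniform of the groups. The same sign of change held for 2597 to 2628 of the 2630 genes, where genes no longer tested count against. The calls came from these same libraries, so the signs are no separate support.

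Among named genes, signs turned in TOP2A and MCM7. TOP2A (main log2 fold change 1.18) ranged from −1.33 without KCNC1 to 2.05 without KCNC2. MCM7 (main 0.24) ranged from −1.15 without KCNC1 to 0.93 without KCNC2, and was −0.12 with limma-voom, −0.13 and −0.12 with the block (all libraries and pairs only), −0.12 with crossed numbers, −0.11 with blocked DESeq2 and −0.14 with blocked limma-voom. The mean log2 fold change of the cell cycle list ranged from −1.77 without KCNC1 to 1.14 without KCNC2, because the KCNC libraries lie on opposite sides of KC. Without KCNC2 the mean also turned in melanocyte (2.16 to −0.40), neural plate border (0.84 to −0.51), WNT (0.84 to −0.88), neuron (0.65 to −0.86), FGF and ERK (0.25 to −0.28) and Notch genes (0.10 to −0.73), none of which passed there. It turned as well in cell cycle genes with the block (−0.29), neuron genes with the stricter filter (−0.34) and Notch genes with no filter (−0.12) or with the block (−0.11). Neural plate border genes (mean 0.84) passed upward in fry, which tests a list against no change. Camera, which compares it with other genes, pointed down without passing. The cause of the other sign changes was not tested.

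With a correlation estimated per list, 0 of 27 list tests passed, against 15, and 12 to 18 passed under the other alternatives. Under library totals, RLE and upper quartile scaling all 92 named genes kept their direction and their side of the threshold. With the stricter filter the immune cell list had too few tested members for a value, and genes that a filter removed have none there. Thinning all libraries to the smallest total left 2567 genes changed. In the simulation, where only 200 of 13876 genes were changed, 2-fold changes were recovered in 0% of genes. In the data 2225 of the 2630 genes called changed at least 2-fold, so some smaller changes passed.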

Other observations

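Every test of an explanation in this part was chosen only after the result was seen, and the genes named here were chosen after their values were seen. KCNC1 and KCNC2 are 1 library each, so their differences have counting intervals (95%, exact, CPM of library totals) and no test of spread. ELF3, MMP1 and TMPRSS4 were among the genes furthest apart between KCNC1 and KCNC2. ELF3, an epithelial transcription factor, stood at 0.446 CPM (0.193 to 0.879) in KCNC1 and 242 CPM (238 to 247) in KCNC2, against a KC mean of 1.78 CPM. MMP1, a secreted collagenase, stood at 0.725 CPM (0.386 to 1.24) and 811 CPM (802 to 820), with a KC mean of 32.3 CPM. TMPRSS4, a membrane protease, stood at 0.446 CPM (0.193 to 0.879) and 253 CPM (248 to 258), with a KC mean of 6.57 CPM. All 21 epithelial junction genes were higher in KCNC2, by a median of 5.29 on the log2 scale.

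Genes of DNA replication and division were higher in KCNC1. CDC6, which loads the replication helicase, stood at 88.5 CPM (84.2 to 92.9) in KCNC1 and 4.63 CPM (3.99 to 5.34) in KCNC2, against a KC mean of 91.7 CPM, and KIF11, a spindle motor, at 198 CPM (191 to 204) and 12.1 CPM (11.1 to 13.3), against 60.7 CPM. SLC14A1, a urea transporter, stood at 230.3 CPM (223 to 237) and 5.42 CPM (4.72 to 6.19), against 0.251 CPM. All 26 cell cycle genes were lower in KCNC2, with a median log2 difference of −2.86, and all 16 cholesterol synthesis genes, with a median of −1.26. Neuron genes were higher in KCNC2 in 7 of 10 members, with a median of 2.28.

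KC3 lay between KC1 and KC2 in 97.2% of the 426 genes over 2-fold apart between them, against 13.8% and 13.0% for the other arrangements of the KC libraries. Pooled sequencing reads are argued against, since KC3 deviated from a weighted mean by 22.8 counting variances on average and pooled reads allow at most 2. A pool of RNA or cells of KC1 and KC2, made before the library, may explain the pattern. Of 25 held-out genes, 76.0% lay nearer a linear mix with a weight of 0.53 for KC1 than a log interpolation. Median absolute log2 errors were 0.184 and 0.301. These genes were chosen for a gap between KC1 and KC2, which favours a KC3 value between them. Elsewhere KC3 could lie beyond both, as for NOTCH1 (normalized CPM of 420 in KC1, 429 in KC2 and 517 in KC3). The 22.8 counting variances do not decide on such a pool, as the spread of library making was not measured. A separate culture in an intermediate state stays open, as KC3 had 0 genes over 2-fold beyond both other KC libraries, against 123 for KC2 and 53 for KC1, and no number is known in advance for such a culture. If KC3 were a pool it would add no independent replicate, and without KC3 34 genes changed.

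Keratinocyte transcripts remained in KCNC, at a median of 0.886% of the KC level in KCNC1 and 20.2% in KCNC2 over 43 basal, simple-epithelium and junction genes. Unchanged keratinocytes as the whole source would leave these genes at a common percent, and only 46.5% of them in KCNC1 and 51.2% in KCNC2 lay within 2-fold of their median, against all 43 in each KC library set against the others. The lowest of the 43 stood at 0.363% and 2.90% of KC, so a smaller share of unchanged keratinocytes may be present. In KCNC1 several keratins lay near that lowest value, as such a share would leave them (KRT5 0.395%, KRT14 0.485%, KRT6A 0.447%, KRT17 0.447%). In KCNC2 these keratins ranged from 2.90% to 12.2%. Other genes stood far higher in KCNC1, with an upper quartile of 3.46% and ITGA3 at 86.6%. Changed cells may express such genes too, so the spread over the 43 cannot exclude a small share. FGFBP1, outside the 43 and among the largest decreases, stood at a normalized 4.24 CPM in KCNC1 and 4.90 CPM in KCNC2, against 1085 ± 74.4 CPM in KC. In KCNC2 that was a lower share of KC than for any of the 43. A share of unchanged keratinocytes in KCNC2 would thus lie below 2.90%, too low to give the median of 20.2% by itself. Keratinocytes that had changed in part were not tested.

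Of mesenchymal genes 13 of 20 were higher in KCNC, of neural crest specifiers 7 of 14 (2 lower) and of surface genes 8 of 14 (1 lower), all 3 lists with adjusted p = 0.460 with an estimated correlation, and other cells in the cultures are candidate sources beside the induction itself, which the groups cannot separate from outgrowth. Pigmented melanocytes as the whole source are argued against by 5 pigment genes chosen after their values were seen. Their median ratio to KC was 0.0739 in KCNC1 and 0.984 in KCNC2, where PAX3 had 456 and 365. DCT, 1 of the 5, went the other way in KCNC2 (5.74 CPM of library totals, against 0.0811 to 0.308 in the KC libraries, and no counts in KCNC1). Among melanocyte genes outside the 5, RAB38 fell, while GPR143 and SLC45A2 rose. GPR143 stood at a normalized 18.1 CPM in KCNC1 and 46.4 CPM in KCNC2, against 1.42 ± 0.266 CPM in KC. Dermal fibroblasts stay open, with DCN at a ratio of 0.536 in KCNC1 and 56.5 in KCNC2 and LUM at 2.77 and 363. The ratios in KCNC1 rest on 6 counts of DCN and 4 of LUM, so both were near absent there. COL1A1 stood at 2738 CPM of library totals in KCNC1 and COL3A1 at 4.13 CPM. In KCNC2 DCN stood at 35.3 CPM, LUM at 29.1 CPM, COL1A1 at 2988 CPM and COL3A1 at 78.0 CPM. KCNC1 is 1 library, so its low DCN and LUM do not settle the source for the group. LUM had 5, 2 and 0 counts in KC1, KC2 and KC3, so its ratios are uncertain. Outgrowth of rare cells already in the KC cultures stays open. The 56 genes looked at were chosen for a log2 fold change over 5, which by itself places them low in KC. A rise from the lowest upper limit (0.228% of the KCNC level) to the whole culture is 8.78 doublings of the share. Loss of other cells would lower the number of cell doublings needed, and their growth would raise it. Neither a doubling rate nor a loss of cells was measured. The 56 genes stood in KC at no common percent (0.168% to 2.87%, interquartile range 2.46 on the log2 scale). Rare cells as the only source of these transcripts in KC would not give that, and keratinocytes that express some of them were not tested.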
